A study of Homo sapiens with 6 samples.

How the data were processed

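RNA was measured in 6 libraries from SCVI-273, a human induced pluripotent stem cell line, which had been differentiated to cardiac progenitor spheres. The line is named in the labels' titles, while the columns of the count table name it Line1, with the word repeat; columns were matched to titles by the library number both carry, and the gravity in the 2 names agreed. The labels call the cells cardiomyocytes. They were cultured for 3 days on the International Space Station, with 3 libraries from microgravity and 3 from an on-board 1 g condition. Per the labels' protocols, cDNA was made from 2 ng of total RNA with a SMART-Seq v4 low-input kit, fragmented with Nextera XT and sequenced as single reads. This chemistry amplifies full-length cDNA by PCR, does not mark the strand and carries no molecular identifiers, so reads are not independent molecules, and reads of overlapping antisense genes cannot be told apart. Intervals and floors that rest on counts cover counting error only.

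The deposited table holds raw read counts per Ensembl gene, with 1 column per library and no normalization. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.7.3a, HTSeq and the genome build GRCh38; the version of HTSeq, the annotation release and the strand setting are not given in the sources used here. The table has 58051 genes, of which 22179 had no count in the 6 libraries, and 0 rows named no gene. Gene names were taken from the table, and 56948 identifiers matched a reference list of current symbols. Coordinates are those of GENCODE 29 on GRCh38, 1-based. Total counts ranged from 11845772 to 26789934 per library.

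Groups were taken from the gravity label. The labels give no batch, no replicate numbers and no pairing, so replicates were numbered in the order of deposit and no block was fitted. Nothing states that the libraries of a group came from separate cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise: the chi-square per gene was at least 9.22 for every pair, over genes with a sum of at least 20 counts.

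Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr (minimum count 10, minimum total 15), robust dispersions and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the 15443 genes tested and a threshold of 0.05. Normalised counts (CPM, scaled per library) use the TMM library sizes, and log2 CPM for principal components a prior count of 2. Fold changes are microgravity over 1 g, with the standard error implied by the F statistic. Reads shared with near-identical copies, as for ACTG1, FTL, ribosomal protein genes and MT-RNR2, can be split or lost in such counts, and their values are uncertain to that extent.

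The 41 gene lists, the tests, the rule for named genes and the first set of alternative analyses were fixed before the data were examined. The lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 41 lists, and again with a correlation estimated per list and with fry. At the preset value camera compares members with other genes as nearly independent, so its p-values do not measure the spread between libraries. The estimated correlation had a median of 0.115 over the lists. It was 0.953 for the mitochondrially encoded list and 0.716 for the sarcomere list. Named genes are, first, up to 10 genes per direction past the threshold with CPM that did not overlap between groups, a mean of at least 5 CPM in the higher group and an approved symbol. Where fewer than 5 passed, the 5 with the smallest unadjusted p were taken and are said not to pass. Second, up to 4 members with the smallest adjusted p were named from each list past its threshold. The rest were a panel of 18 genes of proliferation, survival and cardiac identity. The rule gave 89 genes. Some of them are not reported here. Any other gene was chosen after its values were seen, which is said beside it. Fits without a library repeat the low-count filter, so the tested members of a list can differ from those with all 6.

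The procedure was tested on simulated counts drawn for the 15443 genes of this comparison, with 200 genes changed in each of 5 runs. It recovered 71.6% of genes changed by 2-fold and 98.2% of those changed by 4-fold, with 50 false calls among 922. A shifted list of 30 genes (log2 0.5) passed camera in 5 of 5 runs, and in 4 of 5 with an estimated correlation; 0 of 200 unshifted lists passed. Changed genes and the shifted list were drawn from genes with a mean of at least 5 CPM. The recovery does not cover genes below that level. The simulated genes varied independently, so this does not test camera under the correlations of real genes. No simulated library lay apart from its group in many genes at once, so the recovery need not hold for these libraries. A count of 0 genes in the real data is therefore no measure of how many genes changed by 2-fold or 4-fold.

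Alternatives were other normalization factors, no filter or a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with and without sample quality weights, non-robust dispersions, mitochondrially encoded genes or the 50 most abundant genes left out, stricter thresholds, and each library left out. Thinning to the smallest library, removal of a per-library trend on transcript length and GC, and an estimated correlation without 1 g replicate 2 were added after seeing the data. Single measures of libraries were compared with a two-sided exact permutation test, which cannot give a p below 0.1 with 3 against 3.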

Results

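Human cardiac progenitor spheres grown for 3 days in orbit, either in microgravity (n = 3 libraries) or at an on-board 1 g (n = 3), were profiled by RNA sequencing of low-input total RNA. The microgravity libraries held 11845772, 18079232 and 24622131 counts and the 1 g libraries 15091055, 26789934 and 22230262. The title of the series places the comparison in the context of survival and proliferation of the cells in space. Both groups flew, so the contrast is of gravity level within flight.

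Transcripts of the contractile apparatus, calcium handling, cholesterol synthesis and nuclear encoded oxidative phosphorylation were higher as groups in microgravity, and mitochondrially encoded transcripts, ribosomal protein transcripts and immediate early genes were lower. These are calls of camera with a preset correlation, and the smallest adjusted p = 0.338 with an estimated correlation. No single gene passed the threshold in edgeR's quasi-likelihood test: 0 of 15443 genes, with a smallest Benjamini-Hochberg adjusted p of 0.103. At an unadjusted p under 0.05 there were 1838 genes, 911 higher and 927 lower, where 772 would be expected by chance. DESeq2 called 320 genes (142 higher, 178 lower), limma-voom 0 and limma-voom with sample quality weights 205. Without 1 g replicate 2, edgeR called 645 genes (354 higher, 291 lower), and without 1 g replicate 1 it called 21. The CPM of the groups did not overlap for 2828 genes (18.3%), where chance gives 10% for 3 against 3.

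The first principal component held 32.6% of the variance and separated the groups, but narrowly. Its scores were -21.6, -45.6 and -19.2 in microgravity and 54.0, -15.2 and 47.6 at 1 g. The second, with 22.9%, set 1 g replicates 1 and 3 apart from each other. The 1 g replicate 2 library had a mean Pearson correlation across genes of 0.966 with the microgravity libraries and 0.951 with the other 1 g libraries.

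**Figure D1:**
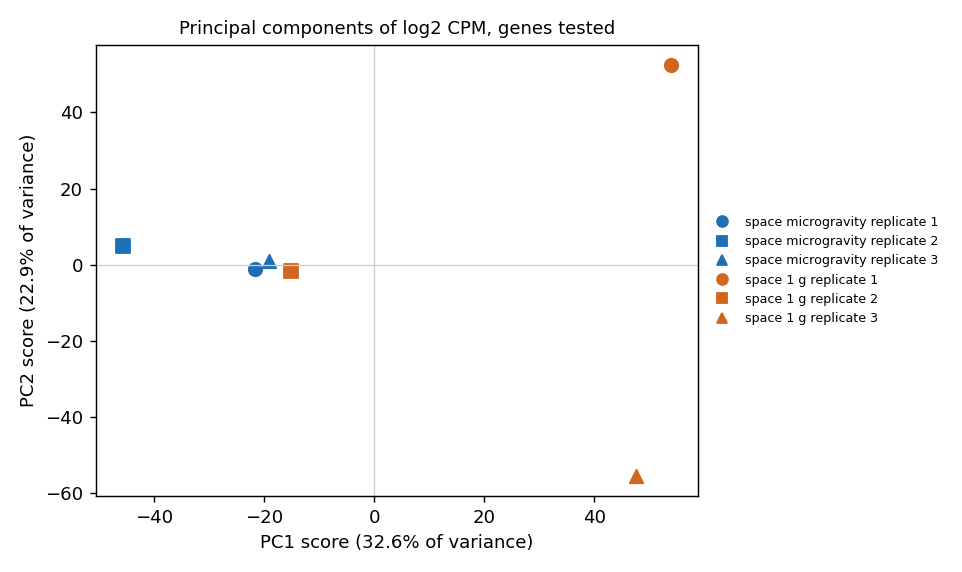
Scores of the 6 libraries on PC1 (x axis, 32.6% of variance) and PC2 (y axis, 22.9%) of log2 CPM; colour gives the group and shape the replicate. The 1 g replicate 2 library, at -15.2 on PC1, lies beside the microgravity libraries.

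The genes with the strongest single evidence did not pass (edgeR adjusted p = 0.103 for each). Higher in microgravity were KCTD12 (ENSG00000178695, chromosome 13, 76880166 to 76886390, GRCh38), at 205 ± 16.0 CPM against 94.1 ± 23.8 (SD, n = 3 each), and TECRL (ENSG00000205678, chromosome 4, 64275257 to 64409468), at 118 ± 16.5 against 51.0 ± 13.4 CPM. TECRL is a gene in which mutations cause an inherited arrhythmia. PDK1 (ENSG00000152256, chromosome 2, 172555373 to 172608669), a kinase that inhibits pyruvate dehydrogenase, was at 871 ± 26.7 against 584 ± 11.9 CPM. The log2 fold changes of PPP1CB (ENSG00000213639, chromosome 2, 28751640 to 28802940) and UBR3 (ENSG00000144357, chromosome 2, 169827458 to 170084131) were 0.61 ± 0.09 and 0.93 ± 0.15 (SE). Lower in microgravity were cytoplasmic gamma-actin, ACTG1 (ENSG00000184009, chromosome 17, 81509971 to 81523847), at 855 ± 49.9 against 1613 ± 206 CPM, and ID1 (ENSG00000125968, chromosome 20, 31605283 to 31606515), a target of BMP signalling, at 124 ± 1.66 against 285 ± 80.9 CPM. CCN1 (named CYR61 in the table, ENSG00000142871, chromosome 1, 85580761 to 85583962), a matricellular protein gene, had a log2 fold change of -0.87 ± 0.14. The mitochondrial ribosomal RNAs MT-RNR1 (ENSG00000211459, mitochondrial genome, 648 to 1601) and MT-RNR2 (ENSG00000210082, 1671 to 3229) had -1.18 ± 0.17 and -1.48 ± 0.23. ACTG1 and MT-RNR2 share sequence with pseudogene copies.

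Of the 41 gene lists, 16 passed camera, 8 higher and 8 lower in microgravity. With an estimated correlation 0 passed (smallest adjusted p = 0.338), and in fry 0 passed for movement in 1 direction (smallest adjusted p = 0.109) and 10 for change in either. Of these 10, the endothelial, epicardial, immediate early, cholesterol and ribosomal protein lists also passed camera. G1 cyclins, p53 targets, YAP/TAZ targets, integrins and ribosome biogenesis did not pass camera. The sarcomere and mitochondrially encoded lists were not among the 10 (fry adjusted p = 0.118 and 0.0793 for change in either direction). No list had a member past the threshold over all genes, and 24 had one adjusted over the list alone. The directions of the lists below are therefore those of camera with a preset correlation.

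Sarcomere genes rose as a list: 28 of 29 members had positive fold changes, with a median log2 of 0.48 (camera adjusted p = 1.48e-12; adjusted p = 0.480 with an estimated correlation), and 6 passed adjusted over the list alone. MYH7, the slow myosin heavy chain, was at 241 ± 27.1 CPM in microgravity against 128 ± 64.1 at 1 g. TTN, NEBL and CRYAB had log2 fold changes of 0.58, 0.60 and 0.59. TNNT2 (0.39 ± 0.24), MYH6 (0.38 ± 0.18) and MYL2 (0.79 ± 0.38) did not pass (edgeR adjusted p = 0.575, 0.459 and 0.456). In 1 g replicate 2 the list lay at -0.05 from the microgravity mean, against -0.99 and -0.53 in 1 g replicates 1 and 3. These follow the order of the mitochondrial shares of counts in the 1 g libraries (5.20%, 10.9% and 6.40% in 1 g replicates 2, 1 and 3). So do the calcium handling, cardiac hormone, cardiac transcription factor, nuclear encoded oxidative phosphorylation and S phase lists. The endothelial, epicardial, endoderm, immediate early, glycolysis, cholesterol, NRF2, ribosomal protein and histone lists, which also passed camera, do not. The order was looked at after the values were seen, and an order of 3 libraries can agree by chance. The median was 0.79 without 1 g replicate 2 and 0.28 without 1 g replicate 1, and the list passed in both cases.

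Calcium handling and ion channel genes rose as a list (24 tested, 18 positive, median 0.34, camera adjusted p = 8.23e-06; adjusted p = 0.480 with an estimated correlation), with 6 members past the threshold adjusted over the list alone. The pacemaker channel HCN4 was at 122 ± 17.1 against 59.7 ± 34.0 CPM, and the sodium-calcium exchanger SLC8A1 at 255 ± 7.44 against 161 ± 41.6. PLN, the phospholamban gene, and the channel subunit CACNB2 had log2 fold changes of 0.57 and 1.01. The median was 0.59 without 1 g replicate 2 and 0.21 without 1 g replicate 1. Cardiac hormone and stress genes also rose as a list (11 tested, 9 positive, median 0.32, camera adjusted p = 0.00370; adjusted p = 0.594 with an estimated correlation), with 3 higher and 1 lower adjusted over the list alone. This list is not separate from the sarcomere list, with which it shares MYH7, CRYAB and ANKRD1. MYH7 and CRYAB were among the 3 higher members. HSPB7, a cardiac small heat shock protein gene, was at 1469 ± 84.1 against 799 ± 268 CPM, whereas RCAN1, a calcineurin regulator, had -0.41. NPPA and NPPB had 0.73 ± 0.29 and 0.28 ± 0.28 and did not pass. The call ended without 1 g replicate 1 (median 0.07, adjusted p = 0.0775), and the median was 0.09 without 1 g replicate 3 and 0.82 without 1 g replicate 2. Cardiac transcription factors rose as a list (24 tested, 15 positive, median 0.14, camera adjusted p = 0.0103; adjusted p = 0.594 with an estimated correlation), with 0 members adjusted over the list alone. MEF2A, MEF2C, SMYD1 and IRX4 had log2 fold changes of 0.45, 0.39, 0.49 and 0.50, and NKX2-5 -0.01 ± 0.18. That call also ended without 1 g replicate 1 (median 0.06, adjusted p = 0.387), and the median was 0.27 without 1 g replicate 2. The cardiac progenitor list did not pass (20 tested, median -0.18, camera adjusted p = 0.734). Within it, ISL1, a marker of the second heart field, was at 39.7 ± 2.72 CPM in microgravity against 59.1 ± 11.4 (edgeR adjusted p = 0.224). At an unadjusted edgeR p under 0.05 the list had 3 members higher and 1, ISL1, lower.

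**Figure D2:**
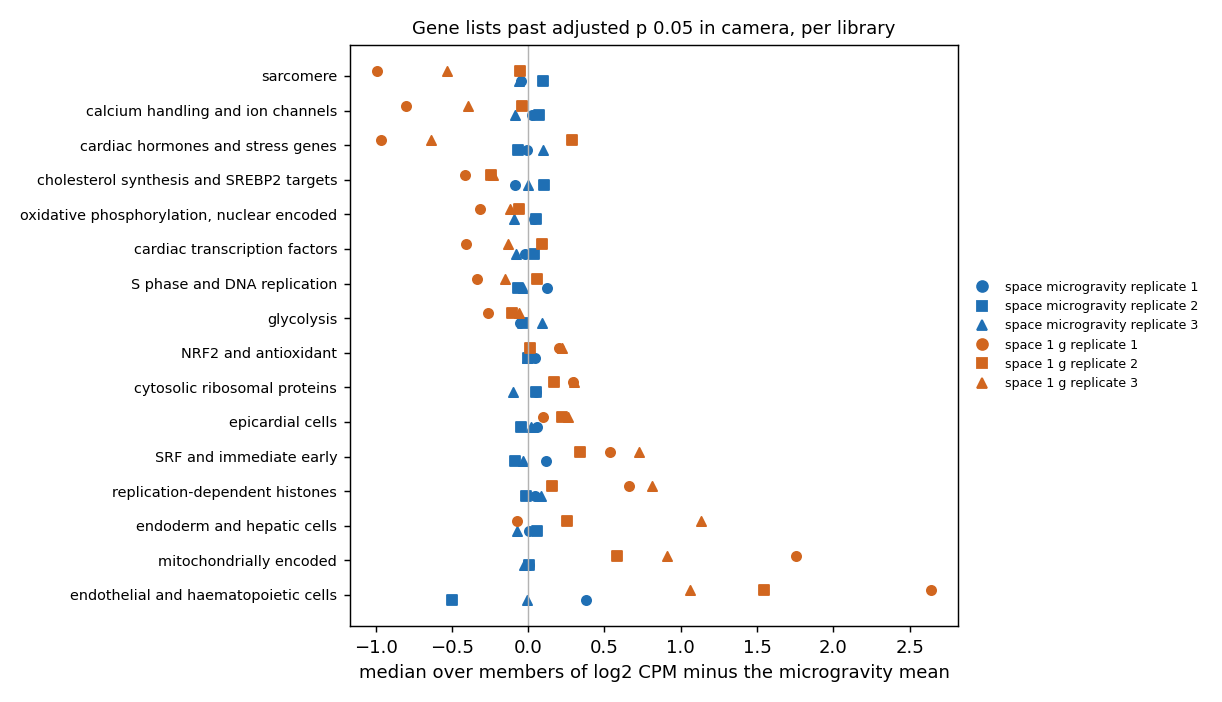
Gene lists past the camera threshold (y axis) against the median over members of log2 CPM minus the mean of the microgravity libraries (x axis), with 1 point per library. In the sarcomere list 1 g replicate 2 lies at -0.05 and the other 1 g libraries at -0.99 and -0.53.

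Mitochondrially encoded transcripts fell as a list: 13 of 13 had negative fold changes and non-overlapping groups, all 13 passed adjusted over the list alone, and the median log2 was -1.20 (camera adjusted p = 5.91e-25; adjusted p = 0.338 with an estimated correlation). MT-CO3, a subunit of cytochrome oxidase, was at 1319 ± 53.2 CPM in microgravity against 3039 ± 1231 at 1 g, and MT-ATP6 at 530 ± 15.3 against 1434 ± 701. MT-ATP8 and MT-ND3 had -2.09 and -1.76. The 1 g libraries differed widely for MT-ATP8, with 711, 328 and 183 CPM in 1 g replicates 1, 2 and 3 against 95.7 ± 14.9 in microgravity. The estimated inter-gene correlation of the list was 0.953, so its members moved almost as a single measure. Their agreement is therefore not 13 separate results. All mitochondrially encoded genes took 3.17%, 3.21% and 3.02% of counts in microgravity and 10.9%, 5.20% and 6.40% at 1 g (exact permutation p = 0.1, the smallest possible). Nuclear encoded oxidative phosphorylation genes went the other way and rose as a list (44 of 47 positive, median 0.17, camera adjusted p = 4.87e-06; adjusted p = 0.594 with an estimated correlation), with 0 adjusted over the list alone. NDUFA13, NDUFB8 and ATP5MG (ATP5L in the table) had 1.38, 0.40 and 0.32. NDUFA13 varied widely, with 28.3, 14.2 and 8.42 CPM in microgravity replicates 1, 2 and 3 against 6.49 ± 0.44 at 1 g. Without 1 g replicate 1 the median of this list was 0.10.

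Cholesterol synthesis genes and targets of the sterol regulator SREBP2 rose as a list (24 tested, 20 positive, median 0.29, camera adjusted p = 5.66e-06; adjusted p = 0.338 with an estimated correlation), and 7 passed adjusted over the list alone. HMGCS1, an enzyme of the pathway, was at 59.6 ± 4.52 against 35.2 ± 12.2 CPM, and STARD4 had a log2 fold change of 0.68. Glycolysis genes rose as a list by less (22 tested, 18 positive, median 0.10, camera adjusted p = 0.00497; adjusted p = 0.594 with an estimated correlation), with 0 adjusted over the list alone. HK2, PFKM, GPI and PGAM1 had 0.63, 0.48, 0.43 and 0.34. This call ended without 1 g replicate 1 (median 0.06, adjusted p = 0.0775) and without microgravity replicate 3 (median 0.06, adjusted p = 0.129).

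Cytosolic ribosomal protein genes fell as a list (68 of 71 negative, median -0.23, camera adjusted p = 9.46e-19; adjusted p = 0.480 with an estimated correlation), and 26 passed adjusted over the list alone. RPL13 was at 371 ± 16.0 against 544 ± 32.0 CPM, and RPL7, RPL6 and RPS7 had -0.55, -0.53 and -0.50. These genes share reads with many pseudogenes.

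Immediate early genes and targets of serum response factor fell as a list (21 of 25 negative, median -0.535, camera adjusted p = 3.18e-12; adjusted p = 0.338 with an estimated correlation), with 12 past the threshold adjusted over the list alone. JUN was at 30.1 ± 1.58 CPM in microgravity and 54.5 ± 2.54 at 1 g, EGR1 at 2.59 ± 0.65 and 11.7 ± 5.46, and FOS at 7.02 ± 3.17 and 24.5 ± 5.98. DUSP1, a phosphatase that switches off MAP kinases, had -1.15. The NRF2 and antioxidant list fell (22 of 27 negative, median -0.17, camera adjusted p = 0.00304; adjusted p = 0.480 with an estimated correlation), with 4 adjusted over the list alone. The ferritin light chain, FTL, was at 6682 ± 452 against 16792 ± 6511 CPM, with 9273 in 1 g replicate 2. HMOX1 was at 55.7 CPM in 1 g replicate 2 and at 447 and 302 in 1 g replicates 1 and 3, against 54.0 ± 8.15 in microgravity. TXN and TKT had -0.51 and -0.47.

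Replication-dependent histone genes fell as a list (9 of 12 negative, median -0.62, camera adjusted p = 0.0209; adjusted p = 0.386 with an estimated correlation), with 2 adjusted over the list alone. H1-2 (HIST1H1C in the table) was at 6.63 ± 0.96 against 12.9 ± 1.72 CPM, and H2BC4, H1-4 and H2AC6 (HIST1H2BC, HIST1H1E and HIST1H2AC) had -2.46, -0.95 and -0.71. Levels were low, with H2BC4 at 0.65 CPM in microgravity against 3.63 at 1 g. Whether these reads follow the total histone mRNA was not tested. This call ended without 1 g replicate 1, 1 g replicate 3 or microgravity replicate 3 (adjusted p = 0.0593, 0.0773 and 0.0693).

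For proliferation, the S phase list rose at the edge of the threshold (23 of 30 positive, median 0.12, camera adjusted p = 0.0495; adjusted p = 0.594 with an estimated correlation), with 0 adjusted over the list alone. The helicase subunits MCM3 and MCM4 were at 221 ± 7.99 against 163 ± 19.6 CPM and 152 ± 16.3 against 123 ± 15.6, and TYMS and ORC1 had 0.38 and 0.68. Without 1 g replicate 1 or microgravity replicate 1 the call ended (medians 0.09 and -0.0007, adjusted p = 0.629 and 0.277), and without 1 g replicate 2 the median was 0.22. The G2/M list did not pass (16 of 30 positive, median 0.03, camera adjusted p = 0.717), with 1 member adjusted over the list alone (ANLN, 0.48, named after its values were seen). MKI67 (0.25 ± 0.28), TOP2A (0.06 ± 0.18) and CCNB1 (-0.09 ± 0.15) did not pass, with 95% intervals of -0.37 to 0.87, -0.33 to 0.46 and -0.43 to 0.25. In the list of G1 cyclins, kinases and inhibitors (19 tested, median -0.03, camera adjusted p = 0.712) the members went both ways: CCND2 was at 307 ± 14.3 against 193 ± 38.1 CPM, and was the only member past the threshold adjusted over the list alone. CCND1 had -0.53 ± 0.22, and the inhibitor CDKN1A was at 3572 ± 207 against 2788 ± 254 CPM (edgeR adjusted p = 0.387 and 0.227).

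For survival, neither the anti-apoptotic list (17 tested, median -0.09, camera adjusted p = 0.372) nor the pro-apoptotic list (23 tested, median -0.05, camera adjusted p = 0.720) passed. Adjusted over the list alone, 1 member passed in each, PPP1R15A (-0.53) and CYCS (0.49), both named after their values were seen. BAX had a log2 fold change of 0.03 ± 0.11, with a 95% interval of -0.21 to 0.27. BCL2, at 0.51 ± 0.68 against 0.75 ± 0.30 CPM, did not pass (-0.49, 95% interval -2.93 to 1.95). The p53 target list did not pass (24 tested, median 0.07, camera adjusted p = 0.125), with 0 adjusted over the list alone.

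**Figure D3:**
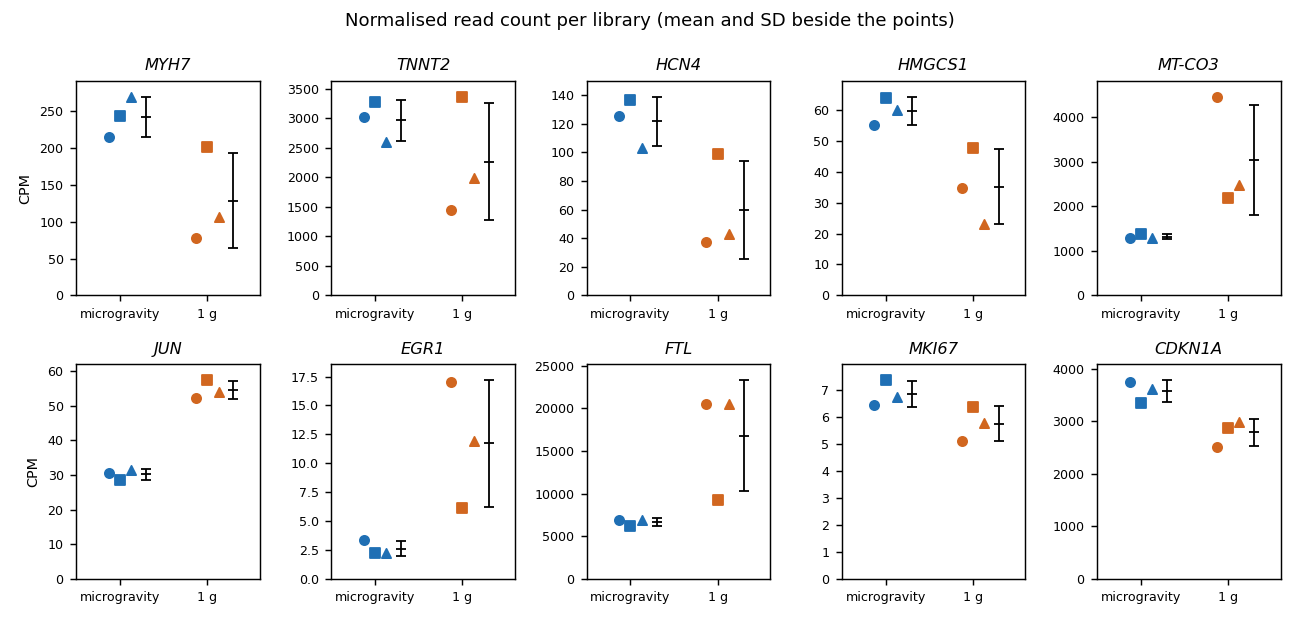
CPM per library (y axis, from 0) in microgravity and at 1 g (x axis) for 10 named genes; points are libraries, shapes replicates, and bars the mean and SD of 3. JUN was at 30.1 ± 1.58 CPM in microgravity and 54.5 ± 2.54 at 1 g, whereas MYH7 at 1 g ranged from 77.8 to 200 CPM.

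Markers of other cell types were measured beside these. Endothelial and haematopoietic markers fell as a list (8 of 8 negative, median -1.69, camera adjusted p = 4.30e-06). With an estimated correlation camera gave an adjusted p = 0.338. Adjusted over the list alone, 3 members passed. Of the 20 markers listed, only these 8 had enough reads to be tested. Their levels were low: CDH5, the vascular cadherin, had 10 counts in the 3 microgravity libraries together and 202 in the 1 g libraries. ERG had 0 counts in microgravity and 62 at 1 g, at least 19.0-fold higher at 1 g against a floor of 3 counts over the group, and with ERG at that bound the median of the list was -1.69. CDH5 and ERG passed the low-count filter through the 1 g libraries, which can favour members with a negative fold change. ESAM and FLT1 had -1.70 and -0.57. For the 3 members with a mean of at least 5 CPM over the 6 libraries the median was -0.57 (-0.70 to -0.12), and none of these 3 passed adjusted over the list alone; ESAM, at 1.82 against 5.81 CPM, did. Without 1 g replicate 1 the median was -0.77 over the 10 members then tested and -1.18 over the same 8. Endoderm and hepatic markers fell as a list (17 of 19 negative, median -0.69, camera adjusted p = 0.00370; adjusted p = 0.594 with an estimated correlation), with 0 adjusted over the list alone. TTR was at 94.5 ± 14.8 against 152 ± 64.9 CPM, with 225 in 1 g replicate 3, and FOXA1, AFP and FGA had -1.59, -1.07 and -0.91. Without 1 g replicate 3 the call ended (median -0.13, adjusted p = 0.486). Epicardial markers fell as a list at the edge of the threshold (8 of 10 negative, median -0.24, camera adjusted p = 0.0491; adjusted p = 0.480 with an estimated correlation). KRT19, at 369 ± 15.6 against 580 ± 90.3 CPM, passed adjusted over the list alone, and LRRN4 and KRT8 had -0.38 and -0.21. WT1 had -2.58 ± 1.34 (SE) on very few reads, at 0.19 CPM in microgravity against 1.00. The epicardial call ended without 1 g replicate 2, 1 g replicate 3 or microgravity replicate 2 (camera adjusted p = 0.128, 0.145 and 0.172). Smooth muscle and fibroblast (median 0.07), neural (-0.20) and pluripotency (-0.20) markers did not pass (camera adjusted p = 0.599, 0.902 and 0.372), with 0 members adjusted over the list alone.

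The other 16 lists did not pass either. In the BMP and TGF-beta list (28 tested, median 0.09, camera adjusted p = 0.910) 3 members were higher and 5 lower adjusted over the list alone, among them TGFBI (-1.10) and ENG (1.41). Adjusted over the list alone, cytokines (median 0.12, camera adjusted p = 0.717) had 2 higher, CXCL12 and VCAM1 (1.06 and 0.84), and 1 lower, ICAM1 (-3.21). Heat shock (-0.02, camera adjusted p = 0.502) had 1 higher and 3 lower, among them HSPA1A (-0.68), and the unfolded protein response (-0.08, camera adjusted p = 0.160) 1 higher and 2 lower, among them DDIT3 (-1.14). Autophagy (-0.11, camera adjusted p = 0.125) had 1 higher and 3 lower, among them SQSTM1 (-1.24). In edgeR, extracellular matrix (0.14, camera adjusted p = 0.207) had 1 of each, COL5A2 (0.95) and MMP2 (-0.96), YAP/TAZ targets (-0.07, adjusted p = 0.498) 2 lower, integrins and actin cytoskeleton (0.02, adjusted p = 0.564) 2 lower, and hypoxia (0.08, adjusted p = 0.125) 1 higher, PDK1. These members were named after their values were seen, to describe the counts. CCN2 (CTGF in the table), a YAP/TAZ target, had -0.29 ± 0.16 and did not pass. Fatty acid oxidation (0.14, camera adjusted p = 0.125), metallothioneins (0.06, adjusted p = 0.734), interferon response (-0.28, adjusted p = 0.287), WNT (0.17, adjusted p = 0.0916), growth factor signalling (0.11, adjusted p = 0.215), NOTCH (0.03, adjusted p = 0.459) and ribosome biogenesis (0.01, adjusted p = 0.720) had 0 members adjusted over the list alone; each value is the median log2 fold change with its adjusted p from camera. The sign of the median, mean and camera direction differed for G1 cyclins, neural markers, integrins, metallothioneins, cytokines, BMP and TGF-beta, and ribosome biogenesis.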

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

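Thinning, the length and GC trend, the estimated correlation without 1 g replicate 2 and the test of other cell types without each library were chosen after seeing the data. The count of 0 genes in edgeR was also 0 with other normalization factors, non-robust dispersions, limma-voom, mitochondrial or the 50 most abundant genes left out and the length and GC trend removed; stricter thresholds gave 0 too, which says nothing, since they could add no call. It was 427 (223 higher, 204 lower) with no low-count filter and 11 (4 and 7) with a filter of 5 CPM. Of those 427, 19 lay outside the genes tested with the filter, and 0 had at most 10 counts in every library. Most were thus genes that the filtered fit also tested, without a call. The count was 320 (142 and 178) in DESeq2, 205 (100 and 105) in limma-voom with quality weights and 5 (2 and 3) after thinning. The cause was not tested. DESeq2 shared 232 calls with edgeR without 1 g replicate 2. Leaving out 1 library gave 0 to 645 genes (0 to 354 higher, 0 to 291 lower), the highest without 1 g replicate 2. Of the 89 named genes, 42 passed in DESeq2 and 52 without 1 g replicate 2, and none that passed anywhere changed direction. Over the other settings 12 to 19 lists passed camera, against 0 with an estimated correlation, 0 in fry and 0 with an estimated correlation without 1 g replicate 2.

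The 16 lists that lost their call with an estimated correlation and in fry had unchanged median log2 fold changes, since only the test differs: S phase 0.12, sarcomere 0.48, calcium handling 0.34, cardiac transcription factors 0.14, cardiac hormones 0.32, endothelial -1.69, epicardial -0.24, endoderm -0.69, immediate early -0.535, glycolysis 0.10, nuclear encoded oxidative phosphorylation 0.17, mitochondrially encoded -1.20, cholesterol 0.29, NRF2 -0.17, ribosomal proteins -0.23 and histones -0.62. With an estimated correlation and without 1 g replicate 2 the medians were S phase 0.22, sarcomere 0.79, calcium handling 0.59, cardiac transcription factors 0.27, cardiac hormones 0.82, endothelial -1.33, epicardial -0.20, endoderm -0.68, immediate early -0.62, glycolysis 0.15, nuclear encoded oxidative phosphorylation 0.22, mitochondrially encoded -1.39, cholesterol 0.28, NRF2 -0.19, ribosomal proteins -0.30 and histones -0.69. Calls also ended, with these medians: S phase 0.12 and epicardial -0.24 with upper-quartile factors, epicardial -0.31 with no low-count filter, S phase 0.12 and histones -0.63 with a filter of 5 CPM in 3 libraries, S phase 0.0788 in limma-voom, S phase 0.12 with mitochondrially encoded genes left out, S phase 0.12 and epicardial -0.33 with the 50 most abundant genes left out, S phase 0.14 and epicardial -0.13 when thinned to the smallest library, epicardial -0.28 and histones -0.53 with the length and GC trend removed. Lists that passed only in an alternative, with these medians, were p53 targets 0.0731, hypoxia 0.0414, fatty acid oxidation 0.15 and WNT 0.15 with no low-count filter, cytokines 0.42 and WNT 0.16 with a filter of 5 CPM in 3 libraries, hypoxia 0.16 in limma-voom. Leaving out 1 library ended or made a call in these lists, with medians of -0.0007 to 0.22 (S phase), 0.0490 to 0.11 (p53 targets), 0.0599 to 0.27 (cardiac transcription factors), 0.0659 to 0.82 (cardiac hormones), -0.0077 to 0.13 (fibroblast), -0.37 to -0.12 (epicardial), -0.92 to -0.13 (endoderm), 0.0145 to 0.22 (extracellular matrix), -0.0713 to 0.15 (hypoxia), 0.0613 to 0.15 (glycolysis), 0.0048 to 0.34 (WNT), -0.69 to -0.47 (histones); the cause was not tested beyond the smaller number of libraries. The lowest S phase median was without microgravity replicate 1. The mitochondrial list has no value where its genes were left out, and DESeq2 was not used for lists.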

Other observations

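The tests of a wrong label, depth, cell composition, damaged cells, transcript length and GC, single libraries as the cause, and other splits of the libraries by gene counts were chosen after the results were seen, as was leaving libraries out of the test of other cell types. The genes in this paragraph were chosen after their values were seen, and none passed in edgeR with all 6 libraries and the low-count filter; without 1 g replicate 2 each of the 5 did (adjusted p = 0.000600 to 0.0312). DTX3L, a ubiquitin ligase gene, had 0 counts in the microgravity libraries and 167 at 1 g, at least 49.3-fold higher at 1 g against a floor of 3 counts over the group. LHX1 had 18 counts in microgravity and 243 at 1 g, and CCNB3 had 159 and 1. ANGPT2, a vascular growth factor gene, had 407, 7 and 302 counts in 1 g replicates 1, 2 and 3 and 27 in microgravity. GATA2 was at 43.5, 10.2 and 31.5 CPM at 1 g and 9.24 ± 0.76 in microgravity.

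No gene passed with all 6 libraries and 645 did without 1 g replicate 2. Depth as the cause is argued against: with every library thinned to the smallest total, 5 genes passed. A wrong label on that library stays open. Each library was placed, over 500 genes chosen without it, from 0 (microgravity mean) to 1 (1 g mean) of the remaining libraries. On these scales 1 g replicate 2 lay at 0.248, the microgravity libraries at 0.127 to 0.450, and 1 g replicates 1 and 3 at 0.842 and 0.744. Genes and scale differ between libraries, and for every other library the 1 g end includes 1 g replicate 2. The positions are therefore not like for like. Against a wrong label, the mitochondrial share of 1 g replicate 2, 5.20%, lay above the 3.02% to 3.21% of the microgravity libraries. Its immediate early list lay at 0.34 from their mean. The values point both ways, and a 1 g culture that differed from the others may account for both.

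The 6 libraries make 10 splits, too few for a share under 0.05. In edgeR the real split gave 0 genes, as did all 10, and the highest other gave 0, so that count says nothing of chance; at an unadjusted p under 0.05 the real split gave 1838 and the highest other 1253. In DESeq2 the real split gave 320 and the highest other 45, so 1 of 10 was as large. For gene lists the real split gave 16 and the highest other also 16, so 2 of 10 were as large. That other split put 1 g replicate 2 with microgravity replicates 2 and 3.

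Mitochondrially encoded transcripts were lower in microgravity while nuclear encoded oxidative phosphorylation genes were not. A larger share of mitochondria-rich cells at 1 g as the whole cause would need the median log2 fold change of the nuclear encoded genes below 0. It was 0.174, and 0.10 to 0.22 with 1 library left out. The 95% bootstrap interval, 0.109 to 0.226, is over genes that vary together and leaves out the spread between libraries. With an estimated correlation camera gave an adjusted p = 0.594 for this list. The median goes against this cause in these libraries but cannot exclude it. Loss of cytoplasmic RNA from damaged cells at 1 g was taken to give nuclear-retained RNAs a fold near the -1.20 of the mitochondrial list. That equal fold is an assumption. The 7 nuclear-retained RNAs tested had a median of -0.0499. They ran from -1.47 (MEG3) to 0.49 (SNHG14), both named after their values were seen. The bootstrap interval of that median, -0.17 to 0.40, is over the RNAs and likewise leaves out the spread between libraries. Values spread this widely, set against an assumed fold, do not exclude damaged cells. With a trend on transcript length and GC removed, the mitochondrial median was -1.16. The state of 1 g replicate 1 (10.9% of counts) as the whole cause is argued against by the median without it, -0.82, and by the 5.20% and 6.40% of the other 1 g libraries. A response to gravity and a difference in RNA handling between the cultures stay open, untested.

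Sarcomere transcripts were higher in microgravity. A lower share of cardiomyocytes at 1 g as the whole cause, with other types in fixed proportions, would shift all their markers alike. Their medians, for members with a mean of at least 5 CPM over the 6 libraries, were -0.69 for endoderm, -0.34 for endothelium, -0.24 for epicardium, -0.20 for pluripotency, 0.13 for fibroblasts and 0.20 for neural cells (Kruskal-Wallis permutation p = 0.0121 over 40 genes, and 0.00610 without the 2 endothelial genes, another being counted with endoderm). With 1 library left out p was 0.00120 to 0.0473 in 5 of 6 cases and 0.510 without 1 g replicate 3, where the endoderm median was 0.03. The difference between the lists thus rested on that library, and a lower share of cardiomyocytes stays open. These p-values permute genes that vary together and leave out the spread between libraries. Unequal shifts could not exclude a lower share in any case, since a single other type may have expanded. With the length and GC trend removed the sarcomere median was 0.49. More endoderm in 1 g replicate 3 as the whole cause is argued against by the sarcomere median without it, 0.46; the median was 0.28 without 1 g replicate 1 and 0.79 without 1 g replicate 2, which showed little of the difference. The sarcomere values of the 1 g libraries also followed the order of their mitochondrial shares. Of the 16 lists past camera 7 did so, the mitochondrial list itself among them. A common cause of the sarcomere and mitochondrial values, a difference in maturation and gravity itself stay open, untested.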
